A study of Mus musculus with 2 samples.

How the data were processed

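H3K9me3 ChIP-seq was done on kidneys of postnatal day 0 mice in 2 biological replicates, each a pool of animals of both sexes; the replicate numbers are those of the labels, and 1 group was formed. Each replicate's reads came from its technical replicates together (2 for replicate 1 and 3 for replicate 2), per the deposited readme files, with a library size range of 300 to 500 per the labels. The labels give no unit for that range.

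Per the readme files, the authors derived each peak list from filtered alignments on mm10 and from control alignments, 1 list per replicate and 1 on both replicates pooled. They drew the replicated list from these 3 lists. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The deposited lists are in narrowPeak format. Their signal value per peak is the authors' own; the readme files do not define that column, although a matching track is called fold change over control. The deposited lists also give −log10 p and −log10 q per peak, from the authors' peak calling. The deposited display score was not used in any result. Because the signal value belongs to each list, it was used to describe, rank or pair peaks and, in 1 test of an explanation, as an assumed ratio to background within the replicated list. Depth is unknown: the files used here give no read counts, so no interval that needs counts of reads was computed. Wilson intervals of 95% on shares of peaks cover the number of peaks alone.

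How the replicated list was made was looked at in the files. All 3670 replicated peaks were found with the same values in the pooled list. All 2689 pooled peaks overlapped by peaks of both replicates (at least 50% of either) were in it, together with 981 peaks (26.7%) that were not so overlapped, with 595 replicated peaks holding no base of a replicate 1 peak and 405 no base of a replicate 2 peak. The rule that kept these is not given in the sources used here, so a peak of the replicated list is not always a peak of both replicates. The values for only those overlapped by both were computed as an added alternative.

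Coordinates are on mm10 and counted from 1. The reference was the GRCm38.p6 sequence with the GENCODE M21 annotation, the same build, and all peaks and genes ended within its chromosomes. Tests used chromosomes 1 to 19, X and Y. Peaks on contigs not placed on a chromosome are given apart, since contig names were not matched to the reference sequences here. Assembly gaps were runs of at least 100 unknown bases.

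Peaks counted as shared when they overlapped by at least 50% of either. Expected numbers came from 1000 random placements of each peak within its chromosome outside gaps (seed 11), with one-sided p for overlap and last exons and two-sided p for annotation classes and base content. Each peak was placed singly, so clusters of peaks were not kept. The SD and p for annotation classes, base content, last exons and Ttn exons can thus be too small, and no rotation was run for them. The smallest p these permutations can give is 0.000999 one-sided and 0.002 two-sided. Signal values of shared peaks were compared by rank and linear correlation with 100000 permutations. For annotation, a peak midpoint was put in the first fitting class of promoter (1 kb either side of a start site), exon, intron and intergenic, using protein-coding genes. For gene lists, all peaks of a chromosome were rotated together, which keeps both genes and peaks clustered, and list members overlapped by at least 1 bp were counted. The p-values were two-sided and adjusted by Benjamini-Hochberg over all 27 lists. With 1000 rotations the smallest adjusted p that a list passing alone could have is 0.0539, so a run with 10000 rotations was added. For zinc finger genes, which here and below are those with Zfp, Zscan or Zkscan symbols, peaks were placed at random within the same genes. Copy number of 50-mers was counted on both strands of the assembled chromosomes, in steps of 10 bp along peaks.

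The 27 lists, the tests and the rule for named genes were fixed before the data were examined, except the tests of protocadherin first exons and of the exons of Ttn, the added alternatives and the tests of explanations for patterns, which were chosen after seeing the data. The tests of explanations were written before their own values were seen. Named were the 20 protein-coding genes with the most covered length, the genes at the 5 peaks of highest signal value, the 3 most covered members of each list, imprinted and germline genes with a peak within 1 kb of a start site (at most 10 each) and overlapped kidney genes. Of 58 imprinted symbols 57 were annotated, as were 27 of 28 of the heterochromatin machinery and all of the other lists.

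Alternatives planned before the data were examined were a −log10 p of at least 5, overlaps of 1 bp and 80%, equal numbers of top peaks, rotation of peaks, merging of peaks within 1 kb, autosomes alone, promoters of 2.5 kb, the pooled list, each replicate's list in place of the replicated one, gene bodies with 5 kb added, promoters in place of gene bodies, random genes matched on length, the 3' part of the gene body (33.3% of it) in place of the last exon, and flanks 10 kb away. The statistics were tested on simulated peaks first. For the overlap of the replicates (12817 simulated peaks), 99.95% of the peaks planted as shared were recovered. For the gene lists (3054 genes), all planted lists, planted together, were called in 10 runs, and 0 lists were called with none planted. A list passing alone could not be called there, as its smallest adjusted p is 0.0539. Simulated peaks were also placed singly, so these runs give no rate of false calls for clustered peaks. For last exons of 422 zinc finger genes, 58.95% of peak length was found where 60.1% was planted, and 22.6% where none was planted and 20.2% came from placement. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.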

Results

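Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of silent heterochromatin, in whole kidney of mice on postnatal day 0. The series held 1 group with 2 biological replicates, both made from tissue of pooled male and female mice of the strain mix B6NTac;B6NCrl. The labels give both the same donor identifier but separate biosamples, so how far the pools were independent is not known. Replicate 1 came from 15 mice and was sequenced as 2 technical replicates. Replicate 2 came from a pool of mice whose number the labels do not give and was sequenced as 3 technical replicates. The values were 4 lists of peaks on the mouse assembly mm10: 1 per replicate, 1 called on both replicates together (the pooled list), and 1 of the pooled peaks that the authors kept as replicated (the replicated list). Sequencing depth was unknown from the files used here. With no second group, the questions the data could answer were where H3K9me3 peaks lay and how far both replicates placed them alike. All permutation p-values below describe positions in these libraries against random positions, not differences between animals.

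Replicate 1 had 13070 peaks covering 3.32 Mb, and replicate 2 had 23628 peaks covering 5.93 Mb, a ratio of 1.81 in peak number. The ratio depended on the threshold: at a −log10 p of at least 5 the lists held 4484 and 4247 peaks, a ratio of 0.947, while at a q-value under 0.05 they held 2394 and 3589. Median peak width was 217 bp in replicate 1 and 214 bp in replicate 2. Both lay near the smallest width of 190 bp, which was also the lower quartile in each list. The pooled list held 22498 peaks and the replicated list 3670, which was 16.3% of the pooled peaks and 28.2% of their covered length. A q-value under 0.05 was reached by 18.3% of the peaks of replicate 1, 15.2% of those of replicate 2, 51.8% of the pooled peaks and 93.3% of the replicated peaks. Replicated peaks were wider than the other pooled peaks (medians of 436 and 240 bp) and had a higher signal value, the authors' own value per peak, with medians of 3.35 (quartiles 3.01 and 3.73) and 2.72 (2.51 and 2.94). No test was made of that difference, because the replicated peaks were chosen from the same list.

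Peaks shared by both replicates were far more frequent than random placement gave, but they were a minority of each list. Of the 12833 peaks of replicate 1 on assembled chromosomes, 2096 (16.3%) overlapped a peak of replicate 2 by at least 50% of either peak, against 37.4 ± 6.12 (SD of 1000 placements), which is 56.1-fold more (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the 23391 peaks of replicate 2, 2092 (8.94%) were shared, 56.6-fold more than the 37.0 ± 6.09 from placement (same p). The share rose with the −log10 p of the peak in its own list, counted against the full list of the other replicate. In replicate 1 it was 9.85% (95% Wilson interval 7.80 to 12.4%) for a −log10 p under 3, 33.1% (30.2 to 36.1%) between 6 and 8, and 24 of 25 peaks at 15 or more. In replicate 2 these shares were 4.13% (3.40 to 4.99%), 25.2% (22.9 to 27.8%) and 22 of 22 peaks. With both lists cut to a −log10 p of at least 5, the share was 12.8% in replicate 1 and 13.3% in replicate 2. Across the 2096 shared peaks, signal values of both replicates were weakly related (Spearman's rho 0.258 and Pearson's r 0.318, each with a permutation p of 1e-05, the smallest that 100000 resamples can give). That relation is across peaks, which are not independent replicates.

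**Figure D1:**
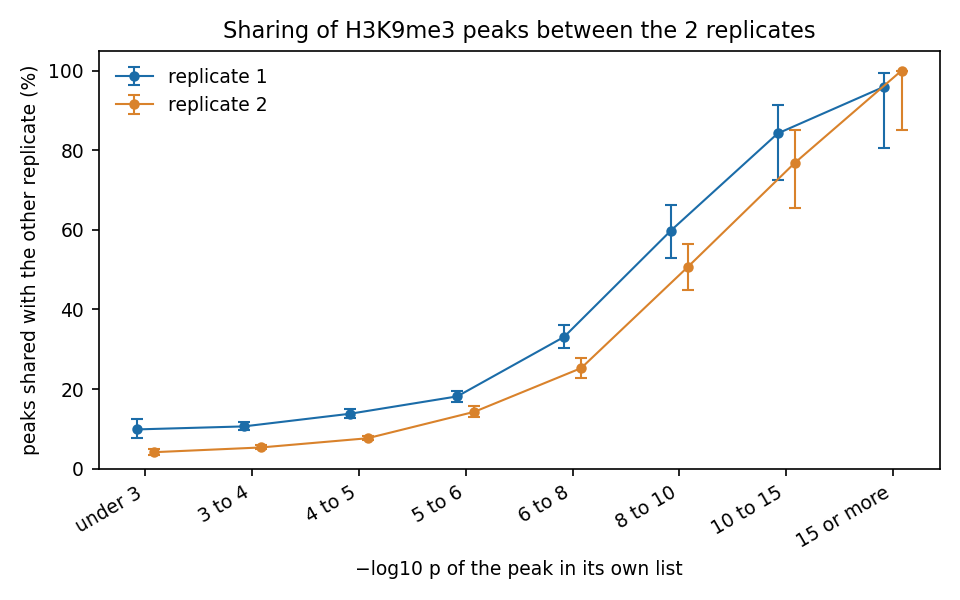
Share of the peaks of each replicate (vertical axis, %) that overlap a peak of the other replicate by at least 50% of either peak, by the peak's own −log10 p (horizontal axis), with 95% Wilson intervals as bars. The share climbs from 9.85% (replicate 1) and 4.13% (replicate 2) below a −log10 p of 3 to 24 of 25 and 22 of 22 peaks at 15 or more.

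The peaks with the highest signal value lay in zinc finger genes, at an imprinted gene and in sequence between genes. The highest value of the replicated list, 8.53, belonged to a peak of 690 bp at chromosome 7, 12010275 to 12010964, between genes and 3965 bp from the pseudogene Vmn1r-ps60. It was followed by a peak of 2118 bp over an exon of Klf14, an imprinted transcription factor gene (chromosome 6, 30956448 to 30958565, signal value 7.86), a peak of 3467 bp over an exon of Zfp180 (chromosome 7, 24103780 to 24107246, 7.29), and a peak of 1185 bp over an exon of Zfp982 (chromosome 4, 147511509 to 147512693, 7.19). The fifth lay on a contig not placed on a chromosome (6.68). Each of these 5 peaks was overlapped by a peak of both replicates.

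By covered length, the leading 1 Mb windows were occupied by gene clusters. The window of chromosome 18 from 37000001 to 38000000 had 85 peaks covering 65549 bp. It holds the beta and gamma clusters of the protocadherin genes and part of the alpha cluster. On chromosome 1, the window from 88000001 to 89000000 had 46 peaks covering 43078 bp, in and around Mroh2a and the Ugt1a genes, which encode glucuronidating enzymes. On chromosome 10, the window from 82000001 to 83000000 had 54 peaks covering 40263 bp, with Zfp873 as its most covered gene. The other windows of the top 10 had Zfp genes among the genes covered, except 1 on chromosome 11 that held Sfi1 and Drg1. The top 10 of 1321 windows with a peak held 16.2% of all covered length. Outside the protocadherin cluster, Mroh2a was the protein-coding gene with the most covered length, with 18 peaks over 18511 bp, or 52.4% of its body (chromosome 1, 88226986 to 88262289).

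Exons carried more replicated peaks than random placement gave and introns fewer. By midpoint, 333 of 3522 replicated peaks (9.46%) lay in exons of protein-coding genes, against 2.88% ± 0.285 (SD of 1000 placements), which is 3.29-fold more (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Introns held 30.5% against 35.2% ± 0.791 (p = 0.002 in the same permutation test). Both directions were also found with the list of each replicate alone, with 1.46-fold (replicate 2) and 1.80-fold (replicate 1) more peaks in exons. Without the listed zinc finger and protocadherin genes the excess in exons was 2.01-fold. The zinc finger list took genes with Zfp, Zscan or Zkscan symbols, so zinc finger genes with other symbols were kept. Promoters, taken as 1 kb on either side of a transcription start site, held 4.91% against 4.07% ± 0.341 (p = 0.034, permutation test), and sequence between genes 55.2% against 57.8% ± 0.827 (p = 0.002, permutation test). These last directions did not hold in the lists of the replicates, where promoters held 3.16% (replicate 2) and 3.27% (replicate 1), fewer than placement gave, and intergenic sequence 62.4% and 62.1%, more than placement gave. Without the listed zinc finger and protocadherin genes, promoters held 3.89% against 3.98% from placement (p = 0.833, permutation test), and intergenic sequence 61.3% against 58.4% (p = 0.002, permutation test). Each peak was placed singly although peaks cluster, so the SD and p-values of these classes can be too small.

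Zinc finger genes, a large family of transcription factors of which many carry a KRAB domain that recruits repressors, were the most numerous marked group. Only those with Zfp, Zscan or Zkscan symbols were in the list. A replicated peak overlapped 87 of 422 of them, against 14.5 ± 4.26 when all peaks were rotated along their chromosomes (5.99-fold; two-sided permutation p = 0.002, adjusted p = 0.027 over the 27 lists). Zfp873 was the most covered, with 10 peaks over 12129 bp, or 73.0% of its body (chromosome 10, 82048123 to 82064745). Zfp110 had 12 peaks over 8700 bp, 55.0% of its body (chromosome 7, 12834761 to 12850577), and Zfp930 had 10 peaks over 8042 bp, 37.4% of its body (chromosome 8, 69209038 to 69230536). The excess was found with each replicate's own list, at 123 genes in replicate 1 (2.57-fold) and 152 in replicate 2 (1.97-fold), both with an adjusted p of 0.027.

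Within zinc finger genes, the peaks gathered on the last exon, which in this family usually encodes the finger array. The last exon held 47.9% of the peak length inside these genes, against 15.9% ± 2.17 for random places in the same genes (3.01-fold; one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the 87 genes, 71 had peak sequence in the last exon. The share was 45.1% in replicate 1 and 40.7% in replicate 2, both with the same p. Peaks were placed singly, so these p-values can be too small where peaks cluster.

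The clustered protocadherin genes, which encode cell adhesion molecules known from neurons, had the highest share of overlapped members. A replicated peak overlapped 39 of 57 gene bodies, against 4.07 ± 7.22 from rotation (9.58-fold; two-sided permutation p = 0.004, adjusted p = 0.027). The excess was smaller in each replicate's own list, at 45 genes against 13.8 in replicate 1 (3.26-fold) and 48 against 22.75 in replicate 2 (2.11-fold), both with an adjusted permutation p of 0.036. The gamma genes share downstream exons, as do the alpha genes, so that their bodies are nested and 1 peak can count for many: Pcdhga1 (chromosome 18, 37661793 to 37841873) was overlapped by 60 peaks over 53830 bp, Pcdhga2 by 59 and Pcdhga3 by 57. The models Gm37013, Gm37388 and Gm42416 span the region and take in all 85 peaks of the window. The call was lost (27 genes against 2.87, 9.41-fold, adjusted permutation p = 0.108), at nearly the same fold, when only replicated peaks overlapped by both replicates were used, and it held at 10000 rotations (adjusted permutation p = 0.0018), both settings chosen after seeing the data.

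First exons, which do not overlap each other except those of Pcdhb21 and Pcdhb22, were tested after the data had been seen. A replicated peak overlapped 25 of the 57, against 0.293 from rotation (two-sided permutation p = 0.002). They were 19 of 21 gamma (p = 0.002 in the same permutation test), 6 of 22 beta (permutation p = 0.012) and 0 of 14 alpha exons (permutation p = 1). Peaks covered 55.2% of the first-exon length of the gamma genes, 6.45% of that of the beta genes and none of that of the alpha genes. The 2 gamma genes with no overlap were Pcdhgc3 and Pcdhgc4, named here after their values were seen, and the 6 beta exons, from Pcdhb15 to Pcdhb22, lay between 37473540 and 37524479, in the part of the beta cluster nearest to the gamma cluster. In replicate 1 the gamma, beta and alpha shares of length were 41.2%, 5.4% and 4.5%, and in replicate 2 they were 48.2%, 8.6% and 3.3%. Some alpha exons were thus overlapped in the replicates' own lists, 6 of 14 in replicate 1 and 5 of 14 in replicate 2 (permutation p = 0.018 each), and 9 of 14 in the pooled list (permutation p = 0.012). The difference between the clusters was not tested, because neighbouring exons are not independent.

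**Figure D2:**
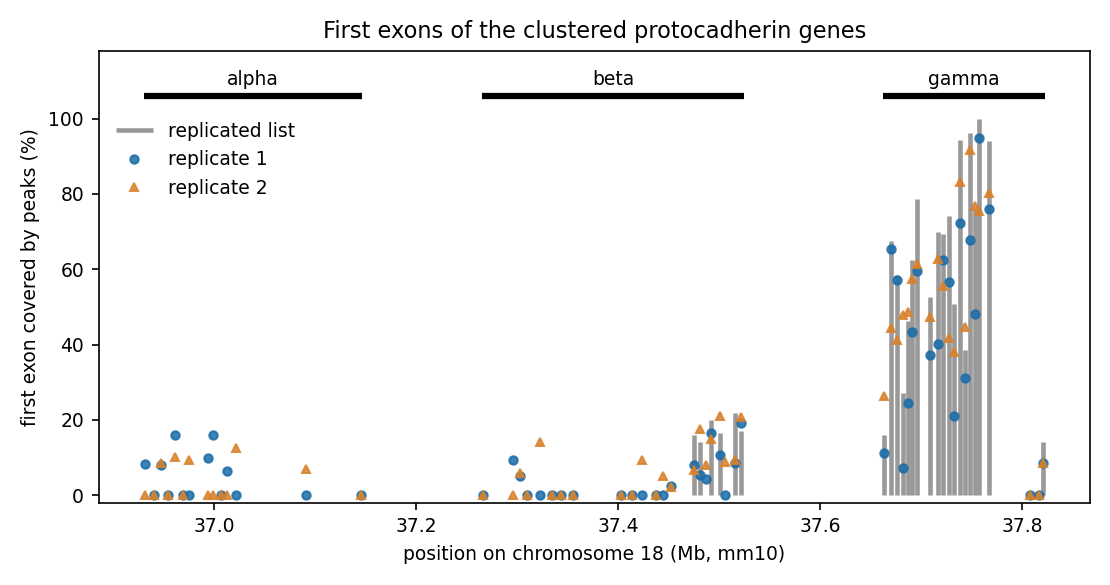
Share of each clustered protocadherin first exon covered by peaks (vertical axis, %) along chromosome 18 (horizontal axis, Mb), for the replicated list (grey lines), replicate 1 (circles) and replicate 2 (triangles), with bars on top for the extent of the alpha, beta and gamma clusters. Coverage in the replicated list is 0 in the alpha cluster and 55.2% of the first-exon length in the gamma cluster.

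Imprinted genes, which are expressed from the allele of 1 parent, were overlapped in 22 of 57 cases, against 3.54 ± 1.86 from rotation (6.21-fold; permutation p = 0.002, adjusted p = 0.027). The excess was found with each replicate's own list, at 31 genes in replicate 1 (2.95-fold) and 32 in replicate 2 (2.02-fold), both with an adjusted p of 0.027. Gnas was the most covered, with 6 peaks over 5594 bp (chromosome 2, 174284320 to 174346744), followed by its antisense transcript Nespas (4 peaks over 2745 bp) and Mest (3 peaks over 2350 bp). Nespas (chromosome 2, 174281237 to 174295436) overlaps Gnas, so some peaks count for both genes.

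At imprinted genes the peaks often lay near a transcription start site. In 15 of the 57 genes a replicated peak lay within 1 kb of one, through 13 distinct peaks. Rotation gave 0.526 such genes (28.5-fold, two-sided permutation p = 0.002, adjusted p = 0.018). This was not particular to imprinted genes. Clustered protocadherin genes (26 of 57 against 0.24) and zinc finger genes (19 of 422 against 2.985) passed too, each with an adjusted permutation p of 0.018. In 12 of the 15 genes the peak overlapped peaks of both replicates. After Klf14, the strongest were at the noncoding RNA gene Meg3 (chromosome 12, 109539211 to 109540257, signal value 5.26, 744 bp from the start site), at Mest (chromosome 6, 30738180 to 30738990, 4.68), Nespas (chromosome 2, 174295268 to 174295721, 4.62) and Gnas (chromosome 2, 174285138 to 174286302, 4.38), and at the cell cycle inhibitor gene Cdkn1c (chromosome 7, 143459504 to 143461262, 4.17). Herc3 and Nap1l5 shared 1 peak (chromosome 6, 58906604 to 58907059, 3.71), which is possible because Nap1l5 lies within Herc3. Mcts2 (chromosome 2, 152686173 to 152686610, 3.65) and Airn (chromosome 17, 12741538 to 12742059, 3.56) followed. The Airn peak was overlapped in replicate 1 but not in replicate 2.

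Vomeronasal receptor genes, which encode pheromone receptors, reached an adjusted p of 0.027 in the permutation test with 18 of 327 genes against 7.74 ± 3.22 (2.33-fold). That call was lost in the permutation test with 10000 rotations, at nearly the same fold (2.29-fold, adjusted p = 0.157). It was also lost with the list of either replicate alone (1.62-fold, adjusted permutation p = 0.189 for replicate 1, and 1.48-fold, 0.0674 for replicate 2). Vmn2r61, with 3 peaks over 1477 bp, was the most covered. Olfactory receptor genes did not pass, with 4 of 1124 genes against 10.8 ± 4.64 (permutation p = 0.0779, adjusted p = 0.421). In the replicates' own lists the counts lay slightly above rotation, at 42 against 37.1 (replicate 1) and 68 against 64.3 (replicate 2), and did not pass either.

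Genes of kidney cell types were overlapped at about the share of all protein-coding genes, of which 952 of 21938 (4.34%) held a replicated peak. Of 92 genes in the lists for nephron progenitors, podocytes, tubule, ureteric bud and collecting duct, and stroma and vessels, 4 were overlapped by a replicated peak, and none of these lists passed (adjusted p = 1 for each in the permutation test). The counts were 0 of 18 nephron progenitor, 1 of 12 podocyte, 1 of 24 tubule, 0 of 20 ureteric and 2 of 18 stromal and vessel genes. The 4 were the endothelial adhesion gene Pecam1 (signal value 3.73), the scaffold gene Magi2 (3.56), the receptor gene Pdgfrb (3.42) and the sodium-glucose cotransporter gene Slc5a1 (3.01), each with 1 peak of at most 643 bp within the gene. For Slc5a1 replicate 2 had no covered sequence. In the replicates' own peak lists, 10 (replicate 1) and 17 (replicate 2) of the 92 genes were overlapped, in each replicate fewer than rotation gave for 4 of the 5 gene lists, and none passed. For the replicated peaks rotation gave at most 1.38 genes for any of these gene lists, so fewer peaks than from random positions could not have been detected.

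No other list passed (adjusted p = 1 for each in the permutation test). No member was overlapped among 39 Hox, 68 histone, 53 keratin, 81 ribosomal protein, 30 housekeeping, 11 adrenal and 21 blood and immune genes. Rotation gave under 1 gene for each of these lists, so fewer peaks than from random positions could not have been detected. Of the gene families, 16 of 361 solute carriers (Slc39a11 the most covered, with 2558 bp), 3 of 73 cytochrome P450 genes, 1 of 61 Serpin, 1 of 42 beta-defensin and 1 of 22 Klr receptor genes were overlapped. Of the cell type lists, 3 of 21 neuron, 1 of 18 muscle and 1 of 14 liver genes were. Among genes that write, read or erase H3K9 methylation and their partners, 2 of 27 were overlapped, namely Atf7ip and Smchd1. Germline genes were overlapped in 3 of 60 cases, against 2.29 from rotation. Within 1 kb of a start site a replicated peak lay at 3 germline genes, of which Dazl was not overlapped in its body. Rotation gave 0.403 such genes (7.44-fold, two-sided permutation p = 0.012, adjusted p = 0.0809). Signal values were 3.39 at Mael, which acts in piRNA silencing, 3.23 at Dazl, an RNA-binding protein gene, and 3.22 at the helicase gene Ddx4.

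**Figure D3:**
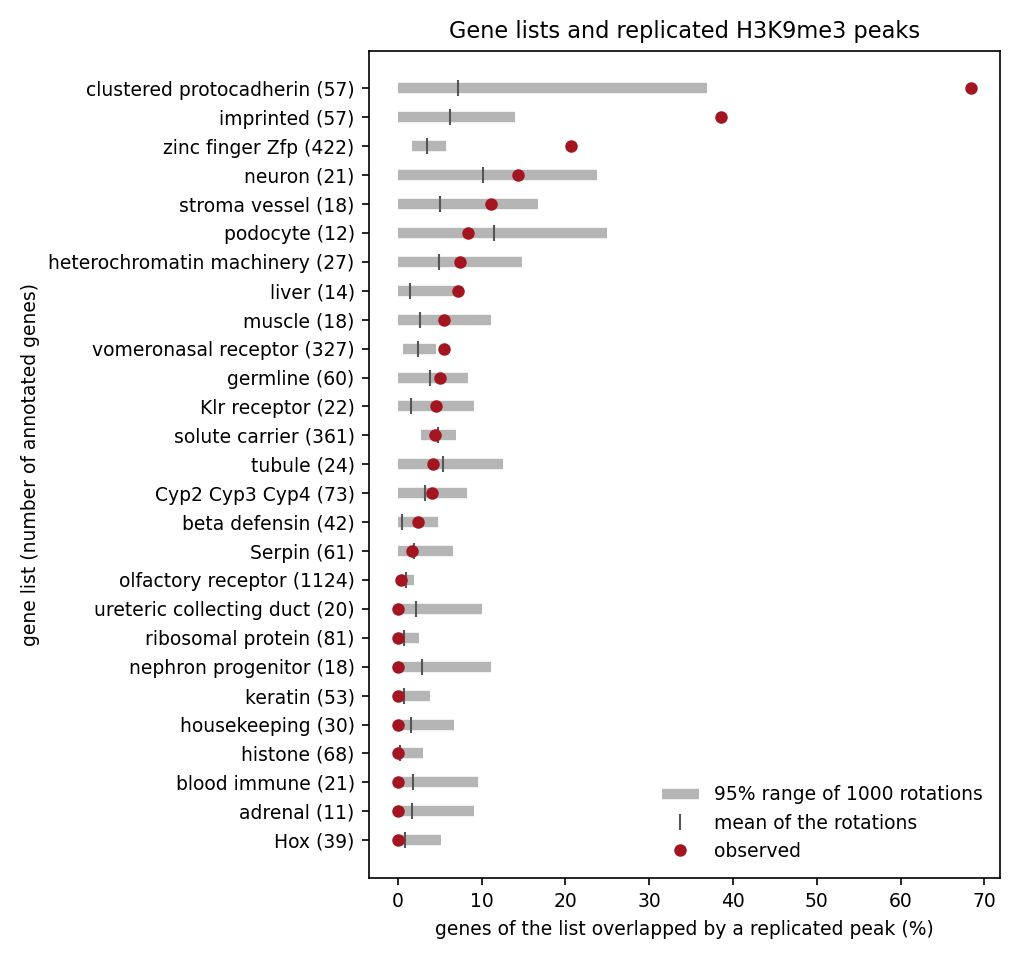
Share of the genes of each list overlapped by a replicated peak (points, horizontal axis, %), with the mean (ticks) and 95% range (grey bars) of 1000 rotations of the peaks, for the 27 lists (vertical axis, number of genes in brackets). Clustered protocadherin (39 of 57), imprinted (22 of 57) and zinc finger genes (87 of 422) lie beyond the range, as do vomeronasal receptor genes (18 of 327), whose call was lost with 10000 rotations.

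Peak density differed between chromosomes. Relative to all autosomes, which held 1.45 replicated peaks per ungapped Mb, the density was 1.79 on chromosome 17 and 1.74 on chromosome 7. Chromosome X held 35 replicated peaks, or 0.214 per Mb, which was 0.147 of the autosomal density, and 12 of the 35 lay in 1 window (31000001 to 32000000). Chromosome Y held 5 peaks, a relative density of 0.0390, and lay lower still in the lists of the replicates, at 0.0151 (replicate 1) and 0.0106 (replicate 2). In the lists of the replicates, X stood at 0.283 (replicate 1, 243 peaks) and 0.222 (replicate 2, 349 peaks), both above the replicated list but below every autosome in the same list. No test was made, because chromosomes are few and are not replicates.

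**Figure D4:**
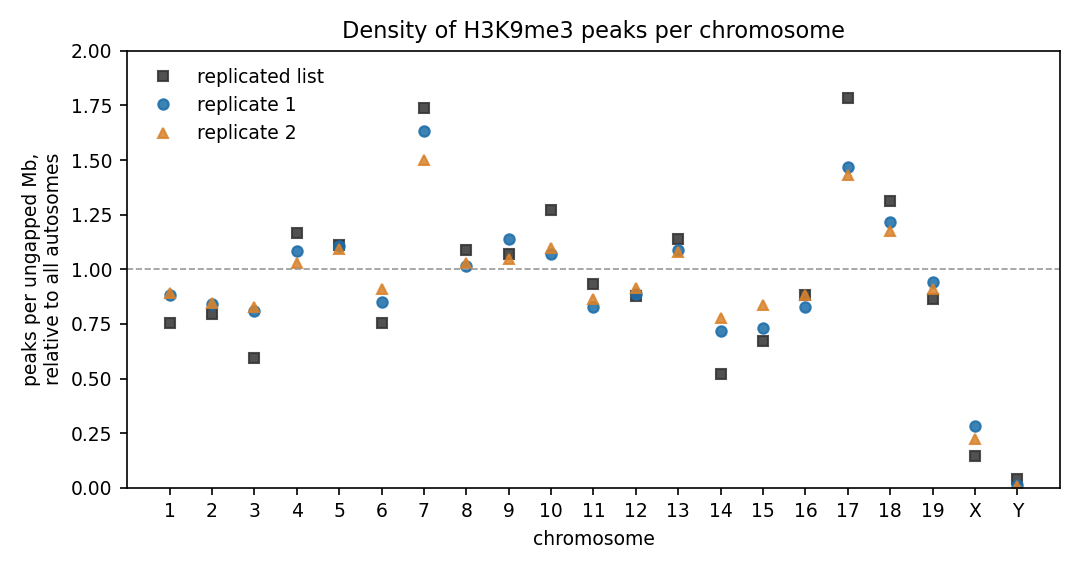
Peaks per ungapped Mb of each chromosome (horizontal axis) relative to all autosomes (vertical axis, dashed line at 1), for the replicated list (squares), replicate 1 (circles) and replicate 2 (triangles). Chromosomes 7 and 17 stand above the other autosomes, and X lies at 0.147 in the replicated list.

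Replicated peaks held less repeat sequence and more GC than random places. Soft-masked bases, the lower-case repeat sequence of the reference, made up 22.0% of peak sequence, against 33.7% ± 0.562 (SD of 1000 placements; two-sided permutation p = 0.002), and 34.65% in flanks 10 kb away. GC content was 45.4% against 42.1% ± 0.123 (p = 0.002, permutation test). Both directions were found in each replicate. The ratio of observed to expected CpG was 0.240 in replicated peaks against 0.194 ± 0.00342 (p = 0.002, permutation test), but in the list of replicate 2 it was 0.1875, below the 0.1935 of placement. Of the 50-mers in replicated peaks 98.9% occurred once on the assembled chromosomes, against 89.6% of 20000 random autosomal 50-mers, which limits what these lists say of repeated sequence.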

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

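The test of an explanation in this part was chosen after the pattern was seen and before its own value was. With 2 replicates in 1 group, the search for libraries standing apart and for differences between groups had nothing to test. What follows is signal on contigs, which the report's tests left out, and loci of very high −log10 p. Of those loci only the ones on contigs were left out of the tests.

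Contigs not placed on a chromosome held 148 replicated peaks, on 13 of the 44 contigs of the assembly. Their density was 19.09 times that of the autosomes, against 8.46 times in replicate 1, 4.62 times in replicate 2 and 5.23 times in the pooled list. The contig peaks were shared by both replicates more often than chromosomal ones, 70.5% against 16.3% in replicate 1 and 64.1% against 8.94% in replicate 2, while their median signal value was 3.08 against 3.36 on chromosomes in the replicated list and, the other way round, 2.86 against 2.72 in the pooled list. None of these differences was tested.

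Some loci combined a very high −log10 p with a modest signal value: 17 replicated peaks had a −log10 p of at least 50, 7 of them on contigs, with a median signal value of 3.09 against 3.35 for the other replicated peaks. The highest −log10 p, 113.5, belonged to a peak in an intron of Drg1 (chromosome 11, 3197498 to 3200118, signal value 3.34), and another, 77.6, to a peak over a ribosomal RNA gene model (chromosome 17, 39843034 to 39846781, 2.33). A candidate explanation is that reads of copies missing from the assembly pile up there in both the immunoprecipitated and the control library: if p comes from a Poisson count and the signal value from its ratio to background, the implied background at these peaks is 15.9 times that of the others by median (121 against 7.59). The implied background was lowest (12.1 to 31.0) at 3 of the 17 whose signal value was not modest (5.69 to 8.53), among them the highest of the list, and the pattern does not describe these. The ratio follows in part from how the peaks were picked and the control reads were not used here, so the explanation stays open, and no biological one was tested.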

How the results depend on the processing

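The alternatives with 10000 rotations, with only the replicated peaks overlapped by both replicates, with first exons only, without loci of −log10 p of at least 50 and without zinc finger and protocadherin genes were chosen after seeing the data. Of the alternative values for 46 results, 315 kept a call with its direction, stayed without a call or stayed within the limits set, 10 lost the call, 11 moved and 9 changed direction. All 14 values for the overlap of the replicates kept the call, at shares of 11.3 to 21.1% for replicate 1 and 6.14 to 13.3% for replicate 2, as did the 10 each for zinc finger and imprinted genes and the 4 for last exons. The 23 lists that did not pass stayed so in all 230 values, although the direction of some turned, such as olfactory receptor genes in the replicates' lists. The excess in exons ranged from 1.46- to 3.58-fold. Requiring a −log10 p of at least 5 left 4484, 4247 and 8270 peaks in the lists of replicate 1, replicate 2 and the pooled list, by construction. The median of replicated peaks over that of other pooled peaks was 2.73 by −log10 q and 1.23 by signal value. These measures have unlike scales, and the value was counted as moved without applying a limit. Promoters changed direction with each replicate's list (3.16 to 3.27%) and the pooled list (3.10%). They did not differ from placement without the listed zinc finger and protocadherin genes (3.89% against 3.98%, permutation p = 0.833), and lost the call at 2.5 kb (9.71%). Sequence between genes changed direction with each replicate's list (62.1 to 62.4%), the pooled list (62.85%) and without those genes (61.3%). The CpG ratio changed direction with the list of replicate 2 (0.1875; 0.2004 for replicate 1). Vomeronasal receptor genes lost the call with 41 to 61 genes in the lists of the replicates, 56 in the pooled list, 15 at a −log10 p of at least 5, 11 with peaks of both replicates, 18 at 10000 rotations, 22 with 5 kb added and 2 in promoters. Protocadherin genes lost it with peaks of both replicates (27), at 9.41-fold against 9.58-fold. Relative density moved to 1.5 to 1.63 on chromosome 7, 1.43 to 1.47 on chromosome 17 (1.86 by covered length) and 0.222 to 0.283 on X in the lists of the replicates. Except where stated, the cause was not tested. Covered length of 61 named genes stayed within 1 SD of the replicates in 141 of 244 values. No paired analysis was possible because there is 1 group. Depth is unknown, so how far it limits the number of peaks and their overlap was not tested.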

Other observations

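The test on Ttn was chosen after its values were seen; the tests of explanations were chosen after the patterns were seen and before their own values were.

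Ttn, the gene of the giant muscle protein titin, was the only overlapped gene of the muscle list and carried 15 replicated peaks over 9381 bp (chromosome 2, 76703980 to 76982547). Of that length 92.3% lay in exons, against 42.5% ± 9.57 for random places in the gene (SD of 1000 placements; one-sided permutation p = 0.000999, the smallest they can give). In replicate 1 the share was 84.2% over 21 peaks and in replicate 2 it was 85.1% over 36 peaks, with the same p. Peaks were again placed singly, so these p-values can be too small. On chromosome 17, in a region chosen after its values were seen, the window from 13000001 to 14000000 held 20 peaks over 14767 bp, with Smok2a and Smok2b as its covered genes, and included the second widest replicated peak, of 5981 bp, 2200 bp from Smok2a. Among genes of the neuron list, which did not pass, Slc17a7, a vesicular glutamate transporter gene, had 1 peak over 1020 bp, all of it in exons. Nrxn1 had 2 peaks over 1360 bp, and Syt1 had 2 peaks over 716 bp, none of it in exons.

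Peaks on the last exon of zinc finger genes could come from reads shared between paralogs, or from a bias toward a GC content or length of exon. In the tests of these, the longest last exon of each gene was taken. Of the 50-mers in the peak parts of these exons 0.334% occurred elsewhere on the assembled chromosomes, against 1.13% in all replicated peaks. Few exact copies were thus found, but the peaks were called on filtered alignments, which may leave mostly single-copy sequence in peaks whatever the cause. Reads from near-identical or unassembled copies were not tested, so shared reads stay open. Last exons of other genes matched on GC (within 1 percentage point) and length (within 1.2-fold) were overlapped at 0.0412 of the rate of zinc finger last exons, 0.685% against 16.6%, which argues against GC content and length. What else the immunoprecipitation or the authors' filtering adds was not tested, and no biological explanation was, since the design has 1 group.

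The few peaks on chromosome X could reflect its lower copy number in a pool of both sexes. Lowering every autosomal −log10 p to 0.75 of its value, and keeping peaks above the level that 95% of the list exceeds, left an autosomal density 5.06 times that of X, but both the scaling and the level are assumed, and how p on X responds to fewer copies was not measured, so copy number stays open. The share of 50-mers that occur once was 0.854 of the autosomal share on X (76.5% against 89.6%). That is too close for exact copies of random 50-mers alone to account for the gap. Near-identical copies and other read lengths were not tested, so a wider effect of mapping stays open. Without peaks in the listed zinc finger and protocadherin genes, X stayed at 0.155 of the autosomal density (33 peaks). Peaks inside these listed genes thus do not account for the gap. Peaks in zinc finger genes with other symbols were kept, as were peaks near listed genes but outside their bodies. A wider effect of the scarcity of zinc finger genes on X, 8 of the 422 listed, thus stays open. Explanations acting together, and the behaviour of the control library on X, were not tested, and no biological explanation was.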
